A study of Homo sapiens with 6 samples.

How the data were processed

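The samples were 6 one-channel Agilent arrays of total RNA (200 ng input, Cy3 label) from HCT116 p53-/- cells reverse transfected with 10 nM siRNA for 96 h. Per the file headers, Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09 made the deposited scanner files, whose processed signal is an intensity after subtraction of background and spatial detrending, with no normalization between arrays. The deposited median spot and local background signals are raw intensity values. Other deposited columns, per the file headers, are flags of 0 or 1, such as well above background, saturated or outlier spot. The authors also deposited a table of log2 values for 34127 probes. Tested against the scanner files, it lay at a median absolute difference of 0.0184 to 0.0198 per array from the log2 processed signal after quantile normalization between arrays. The submitters name limma and Feature Extraction without versions or steps. The headers give array design 026652 on genome build hg19, while the labels give another design number, so probes were named from the accessions in the files and no coordinates are given.

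Each array held 44495 spots, 43118 of them for genes, and no spot was saturated. Between 238 and 444 outlier spots per array were removed. A reference of RefSeq accessions and symbols named 24910 of 34127 probes (73.0%), with 19102 symbols. The 9217 others kept the name in the file. Processed signals were log2 transformed and centred on the 75th percentile of each array, and spots of a probe were averaged. Probes well above background on at least 2 of 6 arrays were kept (23652), and the probe with the highest mean stood for its gene, which left 19283 genes, 14475 with a symbol. Removing outlier spots cost 121 probes. For 3470 genes with several kept probes, probes differed by 2-fold in opposite directions in 0 genes for Mdm2 siRNA and 5 for EZH2 siRNA. Where a group stood below background on all its arrays, the fold is a lower bound against the background limit and is written "at least".

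The choices of comparisons, tests, gene lists and alternatives were made before the data were examined, except those named below as added. A limma fit (lmFit, eBayes) with 3 arms gave the changes: control arm (control siRNA and p53 siRNA), Mdm2 siRNA and EZH2 siRNA, with 3 residual and 3.36 prior degrees of freedom. Pooling both control arrays assumes that p53 siRNA acts little in these cells. The p53 siRNA array was compared with the control siRNA array in a fit with 4 groups and 2 residual degrees of freedom, whose lone arrays are assumed to vary like the replicated groups. Benjamini-Hochberg adjustment ran over all genes, with a threshold of 0.05. An exact test of 2 arrays against 2 cannot go below 0.333, so limma, which borrows spread between genes, was used. Headers place the arrays on 2 slides with 3 arrays each, 1 per arm, so slide is balanced over arms and was tried as a block. Position on the slide follows the arm.

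In all, 22 gene lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists), then with an estimated correlation and with fry. With an estimated correlation camera has only the 3 residual degrees of freedom of the fit. Members were also adjusted over the list alone. The lists were PRC2 subunits and cofactors, PRC1 subunits, HOX genes, developmental Polycomb targets outside HOX, EZH2-silenced genes in cancer studies, intestinal stem cell, pluripotency and intestinal differentiation genes, Wnt/beta-catenin targets, p53 targets other than MDM2, G1/S and replication genes, G2/M and mitosis genes, replication-dependent histones, interferon-stimulated genes, ATF4 and unfolded protein response genes, cholesterol synthesis, mesenchymal transition, epithelial junction genes, cytosolic ribosomal proteins, apoptosis effectors, fibroblast markers, and blood and endothelial markers. Some genes stand in several lists. Medians for p53 siRNA were set beside 10000 random lists matched on signal. The covariance that shared control arrays produce was simulated 100 times from the residual spread.

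Genes were named by a rule: the 3 targets, the 10 highest and 10 lowest genes past the threshold with both arrays beyond the other arm, and up to 4 called members of each list or the 2 with the smallest p. For p53 siRNA the rule took the 5 highest and 5 lowest differences. Since few genes passed, a second rule was added after seeing the data. It took, among the 200 smallest p of a comparison, or the 500 smallest p of both knockdowns, genes well above background on all 6 arrays. Some genes taken by these rules are not reported here.

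Alternatives tried were quantile normalization, median centring, the authors' values, no filter or all 6 arrays above background, the mean of probes, an intensity trend with robust moderation, a 2-fold minimum, slide as a block, other control arms, the 4 arrays of 2 arms alone, replicate number as a block, other probes, and leaving out each array. Added after seeing the data were normexp (offset 50) on median signals, in place of the planned mean signals that the files lack, an adjusted p of 0.1, and slide block, median centring and left-out arrays for the lists and slide block for the targets. Median centring moved the median change of all genes after EZH2 siRNA from 0.015 to -0.107. The deviations of same-numbered Mdm2 and EZH2 arrays correlated at -0.058, so numbers do not pair them.

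The fit was tested on simulated data with spreads drawn from the limma prior. It recovered 54% of 4-fold and 92% of 16-fold changes for Mdm2 siRNA and 56% and 94% for EZH2 siRNA, but 2% and 0% of 2-fold changes, with 4 and 7 calls on unchanged genes. For p53 siRNA against control siRNA it recovered 0% at every size up to 16-fold. Each size was given to 50 genes per comparison, and all arms had the same spread. The real arrays gave only 2 and 0 calls for the knockdowns, so the limit on the unadjusted p was stricter there. These percentages therefore need not hold for the real arrays. IFNE, for example, was 19.69-fold higher after EZH2 siRNA with a limma adjusted p of 0.0772. Camera called a list shifted by 0.5 (adjusted p = 4.47e-13) and 0 of 21 random lists. Genes were simulated as independent, so this does not test lists whose genes move together. Software was R 4.3.3 with limma 3.58.1 and the package data.table (1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.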

Results

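Transcript levels were measured in HCT116 p53-/- cells, a human colorectal carcinoma line that makes no p53 protein, after 96 h of siRNA knockdown. The 6 arrays comprised 1 control siRNA array, 1 p53 siRNA array, 2 Mdm2 siRNA arrays and 2 EZH2 siRNA arrays. MDM2 encodes the ubiquitin ligase best known for degrading p53, and EZH2 encodes the histone methyltransferase of the Polycomb repressor complex PRC2. The series title concerns effects of Mdm2 on chromatin through PRC2 without p53, so the arrays compare loss of either protein in cells where p53 cannot respond. The control siRNA and p53 siRNA arrays together served as the control arm, and their difference counted as spread. Between 67.8% and 71.1% of the 43118 gene spots of an array lay well above background, and the 75th percentile of the processed signal lay between 619 and 878. Changes are given on the log2 scale with the standard error (SE) of limma and n = 2 arrays per arm. Nothing in the labels says whether replicates are separate cultures, so the p-values measure only the spread between these arrays. With 2 arrays per arm, their number limits the precision.

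The first comparison asked whether the Mdm2 and EZH2 siRNAs lowered their own targets. MDM2 fell by 1.81 (SE 0.25) after Mdm2 siRNA, which left 28.5% of the control signal. It stood at 22.1% on slide 1 and 36.7% on slide 2. The adjusted p was 0.000872 over the 3 targeted genes and 0.316 over all genes. A second MDM2 probe was dimmer than background on both Mdm2 siRNA arrays and at least 4.33-fold lower there, while the remaining probe changed by -0.50. EZH2 fell by 1.09 (SE 0.26) after EZH2 siRNA, to 47.1% of the control signal, with an adjusted p of 0.0141 over the 3 targets and 0.121 over all genes. The EZH2 signal left was 61% on slide 1 and 36.3% on slide 2. The EZH2 transcript differed by -0.18 after Mdm2 siRNA (adjusted p = 0.627 over the 3 targets), and the MDM2 transcript by 0.57 after EZH2 siRNA (adjusted p = 0.094), where its other probes gave 0.16 and 0.06.

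**Figure D1:**
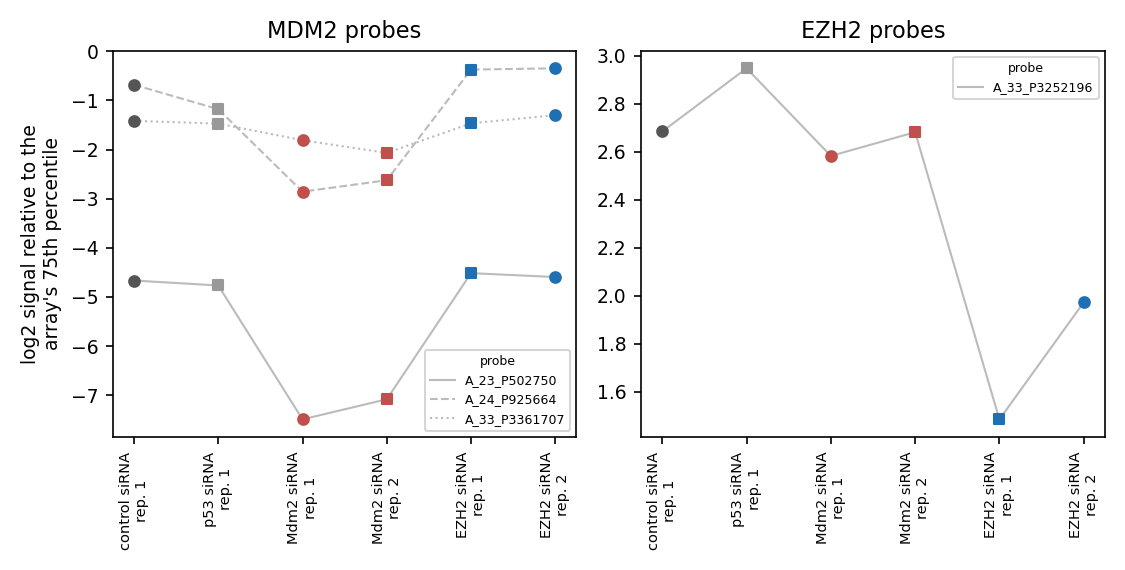
Log2 signal of every MDM2 and EZH2 probe relative to the 75th percentile of its array, one point per array, circles for slide 1 and squares for slide 2, with lines joining the points of a probe. EZH2 lay at 1.49 and 1.97 on the EZH2 siRNA arrays and between 2.58 and 2.95 on the other arrays.

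Mdm2 siRNA was compared with the control arm to ask which transcripts depend on Mdm2 in cells without p53. The clearest loss was in RNA5-8SN5, a small ribosomal RNA gene, by its only kept probe. It fell by 3.61 (SE 0.25, adjusted p = 0.0467), from 3.59 ± 0.24 to -0.02 ± 0.22 (SD, n = 2). Whether that probe follows the level of the ribosomal RNA itself was not tested. SNX31, a sorting nexin of membrane traffic, fell by 3.19 (SE 0.23, adjusted p = 0.0467). It was at least 4.42-fold lower, since it stood above background on neither Mdm2 siRNA array. Both genes were lower on each slide, at -3.94 and -3.29 for RNA5-8SN5 and at -3.35 and -3.03 for SNX31. LIN28B, an RNA-binding protein of embryonic cells that blocks maturation of let-7 microRNAs, was the 1 list member that passed when adjusted over the list alone (2.88, SE 0.44, adjusted p = 0.00807). It rose at least 3.02-fold.

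These were 2 of 19283 genes at an adjusted p under 0.05, 0 higher and 2 lower, with 1596 at an unadjusted limma p under 0.05, where chance gives 964. The remaining genes are therefore given as values, chosen after their values were seen. PIM1, a kinase that promotes survival, was at -2.05 (SE 0.42), and BHLHE41, a repressor of the circadian clock, was at -1.90 (SE 0.21). LEMD1, a testis-expressed gene found in colorectal tumours, was at -2.99 (SE 0.50), LAMB2P1, a laminin pseudogene, at -2.27, and RNF112 at -2.24. On the higher side stood ANGPT2, a secreted ligand of the Tie2 receptor, at 1.92 (SE 0.37), LCMT2 at 1.85 (SE 0.24), TEX261 at 1.61 (SE 0.21) and the zinc finger genes ZNF594, ZNF416 and ZNF91 at 1.84, 1.83 and 1.58. In all, 791 genes differed by at least 2-fold, 405 higher and 386 lower. The 2 arrays lay beyond both control-arm arrays for 8991 genes, or 46.6%, where chance gives 33.3%. Leaving out any of the 6 arrays in turn, or taking slide as a block, gave 0 genes at an adjusted p under 0.05.

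After Mdm2 siRNA, 46 of 51 G2/M and mitosis genes were lower, and the list fell with a median of -0.38 (camera adjusted p = 3.89e-06). PTTG1, the securin of sister chromatids, was at -0.73 and CKAP2, a spindle protein, at -0.71. Of 76 cytosolic ribosomal protein genes, 75 were lower, with a median of -0.28 (adjusted p = 1.87e-06). RPL22 was at -0.63 and RPL3 at -0.48. ATF4 and unfolded protein response genes fell with a median of -0.37 (27 of 32 lower, adjusted p = 0.00155), among them DDIT3, the stress-induced transcription factor CHOP, at -1.83. Cholesterol synthesis genes fell with a median of -0.27 (19 of 24 lower, adjusted p = 0.0103), with the sterol oxidase MSMO1 at -0.87. Interferon-stimulated genes rose with a median of 0.36 (30 of 35 higher, adjusted p = 0.00319), with SAMD9 at 1.45, or at least 2.73-fold, and MX1, an antiviral GTPase, at 2.29, or at least 1.16-fold. Each of these 5 lists had an adjusted p = 0.712 with an estimated correlation, so none of the calls held there. The estimated correlation was 0.56 for G2/M, 0.656 for ribosomal, 0.479 for interferon, 0.246 for ATF4 and 0.0227 for cholesterol genes. Where it lies well above the preset 0.01, the camera p-values with the preset value, here and below, are likely too small.

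The list changes after Mdm2 siRNA did not all hold on both slides. The interferon median was 0.60 on slide 1 and -0.02 on slide 2, and it was -0.12 without Mdm2 siRNA replicate 1 (adjusted p = 0.701). The ATF4 median was -0.04 on slide 1 and -0.60 on slide 2. The G2/M medians were -0.50 and -0.20, the ribosomal medians -0.17 and -0.39, and the cholesterol medians -0.31 and -0.33. Without Mdm2 siRNA replicate 1 the G2/M list had a median of -0.14 (adjusted p = 0.437) and the cholesterol list -0.28 (adjusted p = 0.0792). Without replicate 2 the G2/M median was -0.58 and the interferon median 0.89, both still called. The ATF4 list had a median of -0.19 both without the p53 siRNA array (adjusted p = 0.158) and without Mdm2 siRNA replicate 2 (adjusted p = 0.209), and the interferon list 0.24 without the p53 siRNA array (adjusted p = 0.143). Quantile normalization left the ribosomal list at -0.04 (adjusted p = 0.496).

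EZH2 siRNA was compared with the control arm to ask which transcripts depend on the PRC2 methyltransferase. Genes of mesenchymal transition rose as a list, with a median of 0.86 and 15 of 19 members higher (camera adjusted p = 0.000414). TGFBI, a secreted matrix protein induced by TGF-beta, was at 4.02 (SE 0.49, adjusted p = 0.00251 over the list), at least 10.2-fold higher. The repressors of epithelial genes SNAI2 and ZEB1 were both at 1.27. Adjusted over the list alone, 7 mesenchymal genes rose, also including COL4A1 (1.01), CCN1 (0.89) and ITGA5 (0.86). Epithelial junction genes fell with a median of -0.53 (23 of 33 lower, adjusted p = 0.0103), and 2 of them passed when adjusted over the list alone. These were EPCAM, a surface adhesion protein of epithelia, at -1.17 (SE 0.24), and LLGL2, a polarity protein, at -1.08 (SE 0.22), whose other probe gave 0.08. Each of the 8 lists called after EZH2 siRNA had an adjusted p = 0.491 with an estimated correlation.

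HOX genes, a classical set of Polycomb targets, rose with a median of 0.39 (19 of 28 higher, adjusted p = 0.038). HOXB7 was at 0.78 (SE 0.21) and HOXB2 at 0.81 (SE 0.23), though the other HOXB2 probe gave -0.33. Targets of Wnt and beta-catenin rose with a median of 0.45 (15 of 22 higher, adjusted p = 0.0439), and 4 passed when adjusted over the list alone, 3 higher and 1 lower. JUN, a subunit of AP-1, was at 1.94 (SE 0.31), the Wnt transcription factor TCF7 at 1.18 (SE 0.24) and CCN1 at 0.89, while DKK1, a secreted Wnt antagonist, was at -0.97 (SE 0.21). Ribosomal protein genes fell with a median of -0.45 (73 of 76 lower, adjusted p = 1.03e-09) and G2/M genes with a median of -0.50 (46 of 51 lower, adjusted p = 1.16e-06). RPL3 was at -1.04, RPL23A at -0.95, the mitotic kinase CDK1 at -0.99 and the spindle protein HMMR at -1.06. Cholesterol synthesis genes fell with a median of -0.44 (21 of 24 lower, adjusted p = 0.00285), with INSIG1, which retains the sterol sensor in the endoplasmic reticulum, at -1.47 (SE 0.39). ATF4 and unfolded protein response genes fell with a median of -0.41 (24 of 32 lower, adjusted p = 0.00349), with DDIT4, an inhibitor of mTORC1, at -2.47 and HERPUD1 at -1.47. These lists too had an adjusted p = 0.491 with an estimated correlation. That correlation was 0.12 for epithelial, 0.076 for HOX, 0.0698 for mesenchymal and 0.00537 for Wnt genes.

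EZH2 siRNA replicate 1, on slide 2, carried part of these list changes. The HOX median was -0.04 on slide 1 and 0.57 on slide 2, and it was 0.06 without EZH2 siRNA replicate 1 (adjusted p = 0.469). The Wnt medians were 0.27 and 0.97, and 0.19 without replicate 1 (adjusted p = 0.108). The epithelial medians were -0.24 and -0.54, and -0.17 without replicate 1 (adjusted p = 0.145). Without replicate 1 the G2/M median was -0.27, the cholesterol median -0.26 and the ribosomal median -0.16, all 3 still called. Without replicate 2 the mesenchymal median was 0.23 (adjusted p = 0.0424), the Wnt median 0.83 and the ribosomal median -0.68. The mesenchymal medians were 0.99 on slide 1 and 0.53 on slide 2, the G2/M medians -0.18 and -0.79, the cholesterol medians -0.33 and -0.60, the ATF4 medians -0.23 and -0.49, and the ribosomal medians -0.11 and -0.78. Without the p53 siRNA array the HOX median was 0.30 (adjusted p = 0.144), the Wnt median 0.52 (adjusted p = 0.0613) and the ATF4 median -0.29 (adjusted p = 0.0722), while without the control siRNA array the ATF4 median was -0.63. Quantile normalization ended the HOX call (median 0.35, adjusted p = 0.054). It also ended the epithelial (median -0.41) and ATF4 (median -0.27) calls, both at adjusted p = 0.0667.

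**Figure D2:**
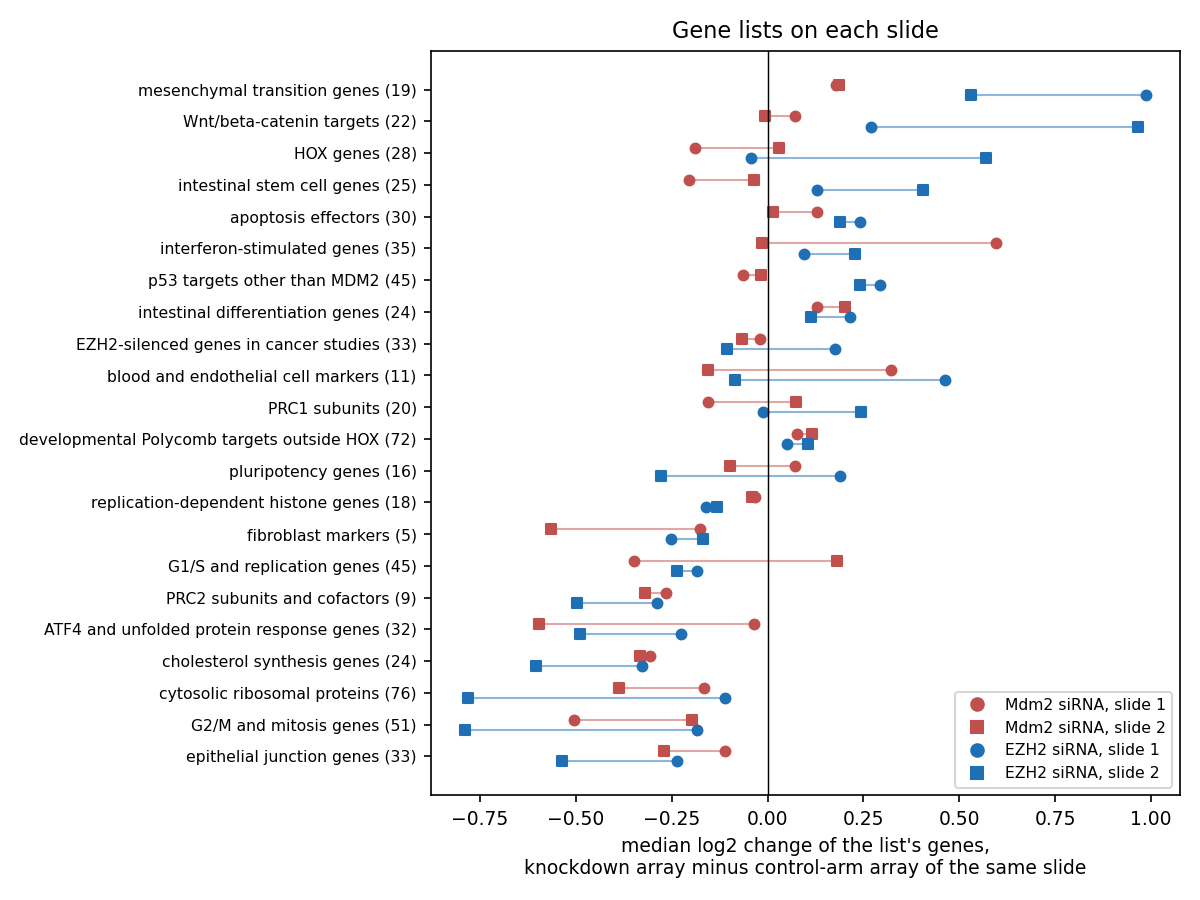
Median log2 change of each gene list, as knockdown array minus the control-arm array of the same slide, in red for Mdm2 siRNA and blue for EZH2 siRNA, circles for slide 1 and squares for slide 2, with the number of measured genes in brackets. After EZH2 siRNA the mesenchymal list lay above 0 on both slides, at 0.99 and 0.53, and the G2/M list below 0 on both, at -0.18 and -0.79.

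Single genes showed large differences after EZH2 siRNA, but limma called 0 of 19283 at an adjusted p under 0.05, with 3551 at an unadjusted p under 0.05, where chance gives 964. The smallest adjusted p was 0.0666, and 279 genes, 134 higher and 145 lower, lay under an adjusted p of 0.1, a limit added after seeing the data. The genes that follow were chosen after their values were seen. IFNE, the epithelial interferon epsilon, was at 4.30 (SE 0.54, adjusted p = 0.0772), and MIR31HG, the host transcript of a microRNA, at 3.59 (SE 0.51, adjusted p = 0.0834). ANGPT2 was at 2.96 (SE 0.37), PAQR9 at 2.83 (SE 0.34) and KBTBD8, an adaptor of a ubiquitin ligase, at 3.12 (SE 0.47). HMGA2, an architectural chromatin protein of embryonic tissue, was at 3.06 (SE 0.28, adjusted p = 0.0666) by its brightest probe, while its other probes lay between -0.39 and 0.56. AGPAT4, a lysophospholipid acyltransferase, was at 3.25, with other probes between -0.37 and 0.41. On the lower side RNA5-8SN5 was at -3.19 (SE 0.25, adjusted p = 0.0666), RDM1, a RAD52-related protein, at -2.85 (SE 0.29) and CCNG2, a cyclin of growth-arrested cells, at -2.69 (SE 0.39). RNF112 was at -2.40, YPEL2 at -2.37 and CLEC11A, a secreted growth factor, at -2.36. In all, 1905 genes differed by at least 2-fold, 1015 higher and 890 lower, and 10102 genes, or 52.4%, had both arrays beyond both control-arm arrays, where chance gives 33.3%. Leaving out EZH2 siRNA replicate 2 gave 758 genes, 336 higher and 422 lower, a fit in which the lone replicate 1 is assumed to vary like the other arms.

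Genes named in cancer studies as silenced by EZH2 did not pass as a list, with a median of 0.19 after EZH2 siRNA (22 of 33 higher, adjusted p = 0.469) and -0.05 after Mdm2 siRNA (adjusted p = 0.672). Adjusted over the list alone, 3 members passed after EZH2 siRNA. Among them FBXO32, an F-box protein, was at -1.79 (SE 0.26) and DKK1 at -0.97. Developmental Polycomb targets outside HOX had a median of 0.09 after EZH2 siRNA (adjusted p = 0.291) and 0.04 after Mdm2 siRNA (adjusted p = 0.553), with the homeobox gene MSX2 at 1.54 (SE 0.27) after EZH2 siRNA. PRC2 subunits and cofactors had medians of -0.37 (adjusted p = 0.114) after EZH2 siRNA, with the histone chaperone RBBP7 at -0.75, and -0.32 (adjusted p = 0.17) after Mdm2 siRNA, with SUZ12 at -0.56. PRC1 subunits had medians of 0.19 (adjusted p = 0.965) and -0.09 (adjusted p = 0.748), with CBX7, a reader of methylated histones, at -1.10 and -0.77, though its other probe gave 0.18 and 0.10. Intestinal stem cell genes had medians of 0.33 after EZH2 siRNA (adjusted p = 0.18), called at 0.45 without EZH2 siRNA replicate 2 (adjusted p = 0.0384) and uncalled at 0.06 without replicate 1 (adjusted p = 0.887), and -0.10 after Mdm2 siRNA (adjusted p = 0.5). Pluripotency genes had medians of -0.01 (adjusted p = 0.965) and -0.11 (adjusted p = 0.867), and intestinal differentiation genes 0.19 (adjusted p = 0.37) and 0.13 (adjusted p = 0.335).

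Targets of p53 other than MDM2, in cells without p53, had a median of 0.26 after EZH2 siRNA (28 of 45 higher, adjusted p = 0.169) and -0.06 after Mdm2 siRNA (adjusted p = 0.854). BBC3, the BH3-only killer protein PUMA, was at -1.32 (SE 0.29) and -1.03 (SE 0.29). Apoptosis effectors had medians of 0.31 (adjusted p = 0.216) and 0.11 (adjusted p = 0.17), the latter called at 0.17 under normexp on median signals (adjusted p = 0.0453) and uncalled at 0.04 without the p53 siRNA array (adjusted p = 0.176), -0.01 without Mdm2 siRNA replicate 1 (adjusted p = 0.437) and 0.19 without replicate 2 (adjusted p = 0.176). G1/S and replication genes had medians of -0.20 (adjusted p = 0.103) and -0.11 (adjusted p = 0.672), and replication-dependent histone genes -0.14 (adjusted p = 0.257) and -0.02 (adjusted p = 0.553). After Mdm2 siRNA the G1/S median was -0.35 on slide 1 and 0.18 on slide 2. It was called in opposite directions when an array was left out, at 0.17 without Mdm2 siRNA replicate 1 (adjusted p = 0.0337) and -0.30 without replicate 2 (adjusted p = 0.000423). Interferon-stimulated genes had a median of 0.31 after EZH2 siRNA (adjusted p = 0.0977), called at 0.44 without the control siRNA array (adjusted p = 0.0113) and at 0.19 with median centring (adjusted p = 0.0437). That median was 0.01 without the p53 siRNA array (adjusted p = 0.284) and 0.09 without EZH2 siRNA replicate 2 (adjusted p = 0.238). After Mdm2 siRNA the HOX median was -0.12 (adjusted p = 0.748), the Wnt median -0.07 (adjusted p = 0.804), the mesenchymal median 0.19 (adjusted p = 0.553) and the epithelial median -0.10 (adjusted p = 0.17), with the tight junction gene CLDN4 at -1.48 (SE 0.29). The 5 fibroblast markers had medians of -0.16 after EZH2 siRNA (adjusted p = 0.384) and -0.37 after Mdm2 siRNA (adjusted p = 0.083). The latter was called at -0.60 without the control siRNA array (adjusted p = 0.0264) and at -0.31 under normexp on median signals (adjusted p = 0.0208), but was -0.14 without the p53 siRNA array (adjusted p = 0.176). Medians were 0.19 and 0.03 for the 11 blood and endothelial markers (adjusted p = 0.317 and 0.804). Median, mean and camera differed in sign for PRC1 subunits and pluripotency genes after EZH2 siRNA, and for EZH2-silenced and pluripotency genes after Mdm2 siRNA, all far from a call. Other medians of uncalled lists also moved or reversed when an array was left out, so their directions are not interpreted.

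EZH2 siRNA was compared directly with Mdm2 siRNA to ask whether the knockdowns differ. Mesenchymal genes were higher after EZH2 siRNA, with a median difference of 0.44 (16 of 19 higher, camera adjusted p = 0.000171, adjusted p = 0.528 with an estimated correlation). Of the 3 that passed when adjusted over the list alone, ZEB1 was 1.73 higher (SE 0.22) and TGFBI 3.01 higher (SE 0.49). Wnt targets were higher by 0.47 (18 of 22, adjusted p = 0.0017, adjusted p = 0.528 with an estimated correlation), and 5 passed when adjusted over the list alone. RNF43, a ligase that removes Wnt receptors, was 1.71 higher (SE 0.30), AXIN2, a feedback inhibitor of the pathway, 1.59 (SE 0.41), JUN 1.46 and TCF7 0.91, while DKK1 was at -1.39 (SE 0.21). HOX genes were higher by 0.38 (23 of 28, adjusted p = 0.0017) and intestinal stem cell genes by 0.32 (19 of 25, adjusted p = 0.0247), both with adjusted p = 0.609 with an estimated correlation. Ribosomal protein genes were lower, at -0.20 (64 of 76, adjusted p = 0.00192, adjusted p = 0.905 with an estimated correlation). On slides 1 and 2 the median differences were 0.69 and 0.32 for mesenchymal genes, 0.40 and 0.63 for Wnt targets, 0.37 and 0.42 for HOX genes, 0.21 and 0.42 for stem cell genes, and 0.08 and -0.44 for ribosomal protein genes.

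Single genes far apart between the knockdowns, chosen after their values were seen, included LEMD1 at 3.19 (SE 0.50), the estrogen receptor GPER1 at 2.85 (SE 0.64), CORO2B at 2.68 (SE 0.34), IFNE at 2.66 (SE 0.54) and EDN1, the precursor of endothelin, at 2.17 (SE 0.49). The other GPER1 probes lay between 0.46 and 2.63, and the other EDN1 probe gave 1.16. Lower after EZH2 siRNA than after Mdm2 siRNA were CLEC11A at -1.88 (SE 0.38), the cytokine receptor TNFRSF8 at -1.84 (SE 0.31) and the nuclear receptor NR4A3 at -1.69 (SE 0.29). Limma called 0 genes at an adjusted p under 0.05, with 1805 at an unadjusted p under 0.05 and a smallest adjusted p of 0.206, and 977 genes differed by at least 2-fold. Arrays did not overlap for 7090 genes, or 36.8%, where chance gives 33.3%. Among the list differences, HOX was 0.28 without Mdm2 siRNA replicate 1 (adjusted p = 0.146) and 0.20 without EZH2 siRNA replicate 1 (adjusted p = 0.161), stem cell genes were 0.21 and 0.18 (adjusted p = 0.178 and 0.704), ribosomal protein genes were 0.12 without EZH2 siRNA replicate 1 (adjusted p = 0.553), and mesenchymal genes were 0.32 without EZH2 siRNA replicate 2 (adjusted p = 0.187). Calls were kept at larger values for stem cell genes without replicate 2 of Mdm2 siRNA (0.49) or of EZH2 siRNA (0.57), for ribosomal protein genes without EZH2 siRNA replicate 2 (-0.47) and for mesenchymal genes without EZH2 siRNA replicate 1 (0.70). Other lists, not called in the planned test, were called with an array left out. These were G1/S genes (-0.31) and G2/M genes (-0.35) without Mdm2 siRNA replicate 1, ATF4 genes (-0.36) without Mdm2 siRNA replicate 2, and G2/M genes (-0.29) and epithelial genes (-0.45) without EZH2 siRNA replicate 2. Interferon-stimulated genes were called in opposite directions, at 0.42 without Mdm2 siRNA replicate 1 (adjusted p = 0.0104) and -0.44 without replicate 2 (adjusted p = 0.000119). Targets of p53 were called without Mdm2 siRNA replicate 2 (0.29), without EZH2 siRNA replicate 1 (0.42), and with all arrays after quantile normalization (0.26, adjusted p = 0.0355).

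The shared response asked whether loss of Mdm2 moves the same genes as loss of EZH2. RNA5-8SN5 was lower in both by its only kept probe, at -3.61 after Mdm2 siRNA and -3.19 after EZH2 siRNA. Genes far from 0 in both, chosen after their values were seen, also included ANGPT2 (1.92 and 2.96), RNF112 (-2.24 and -2.40), LAMB2P1 (-2.27 and -2.62), the circadian transcription factor DBP (-1.79 and -1.84) and the dopamine receptor DRD4 (-1.75 and -2.49). Across 19283 genes, which are not independent replicates, the changes correlated with r = 0.633 and rho = 0.598. A simulation with no effect and shared control arrays gave r of 0.502 and rho of 0.457. Its spread was pooled over the 3 arms. The SD of the log2 difference between arrays was 0.401 in the control arm, 0.563 for Mdm2 siRNA and 0.724 for EZH2 siRNA. The simulation thus overstates what these control arrays add. Of the first 500 genes by p in each comparison, 203 were common and in the same direction. That compares with 132.7 simulated with no effect and 6.5 for independent lists. None was common in the opposite direction, but that count was not simulated. Shared control arrays alone also make opposite directions rarer, so it is not read as support. With a different control array for each knockdown, r was 0.442 and 0.421. For array pairs that share neither a control array nor a slide, r was 0.326 and 0.302. Between the 2 arrays of one knockdown, also with separate control arrays and slides, r was 0.256 for Mdm2 siRNA and 0.417 for EZH2 siRNA.

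**Figure D3:**
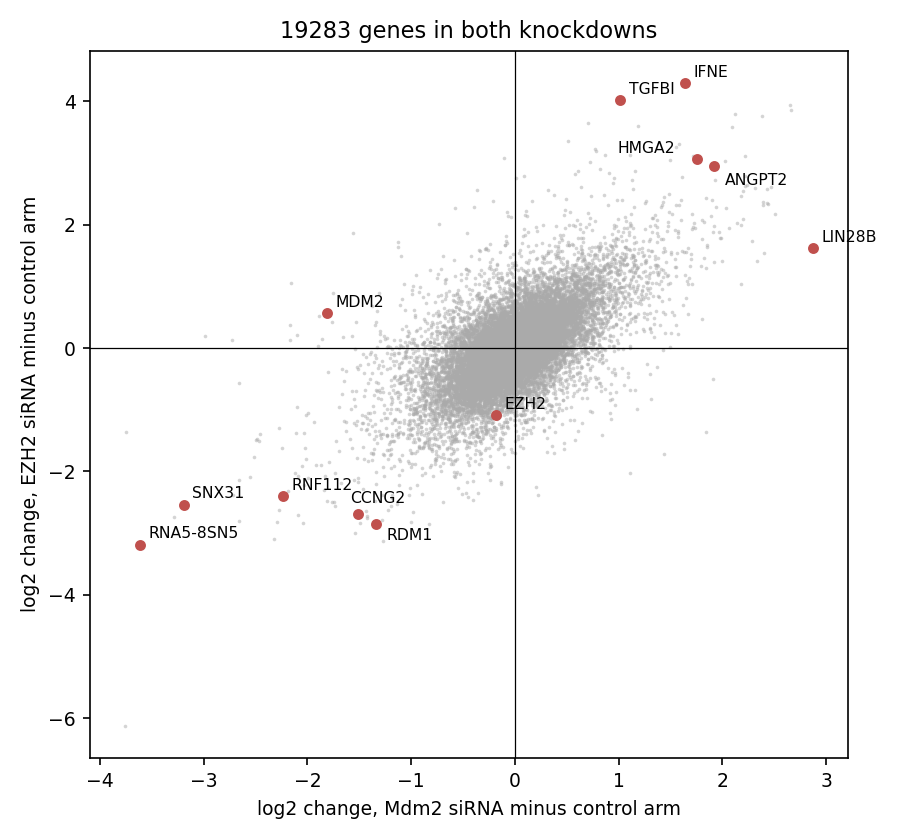
Log2 change of each of 19283 genes after Mdm2 siRNA (horizontal) and after EZH2 siRNA (vertical), both against the same control-arm arrays, which itself raises the correlation of r = 0.633. RNA5-8SN5 and ANGPT2 lie on the same side in both knockdowns, while MDM2 lies at -1.81 after Mdm2 siRNA and 0.57 after EZH2 siRNA; the lowest point is a transcript without a gene symbol.

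The p53 siRNA array was compared with the control siRNA array as a measure of background, since the cells have no p53 protein to lose. The control siRNA array lay on slide 1 and the p53 siRNA array on slide 2, so their difference includes any slide difference. The small proline-rich genes SPRR2A, SPRR2E and SPRR2C, components of the cornified envelope, stood 2.94, 2.54 and 2.44 higher on the p53 siRNA array, and the splicing repressor PTBP2 stood 2.48 higher. SPRING1, a regulator of sterol sensing, was at -2.43, the interferon receptor gene IFNAR1 at -2.25 and the metalloprotease ADAM9 at -1.79. ATF4 and unfolded protein response genes had a median of 0.35 and ribosomal protein genes of 0.14, at percentiles 100 and 99.7 of 10000 lists of other genes matched on signal, and G2/M genes had 0.11 at percentile 99.6. Mesenchymal genes had a median of -0.25 at percentile 0.18, and interferon-stimulated genes -0.13 at percentile 1.83. Members of a list can move together more than matched genes do, so these percentiles may be too extreme. Limma with 1 array on each side called 0 genes, with 218 at an unadjusted p under 0.05, where chance gives 964. The SD of the log2 difference was 0.401 between these arrays, 0.563 for Mdm2 siRNA and 0.724 for EZH2 siRNA. The spread taken from the knockdowns is thus likely too wide for this test. In all, 571 genes differed by at least 2-fold, 321 higher and 250 lower.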

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

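The list differences below come from the planned comparison of the knockdowns, and all tests of explanations in this part were chosen after the results were seen. For 5 lists the direct test of EZH2 siRNA against Mdm2 siRNA was passed with the preset correlation and lost with an estimated one. For Wnt/beta-catenin targets the estimated correlation was 0.00537, below the preset 0.01, yet the camera adjusted p rose from 0.0017 to 0.528. At least for that list, the loss therefore cannot be read as an effect of correlation between genes. The 3 residual degrees of freedom used with an estimated correlation raise the p-values of every list. The smallest adjusted p of any list was then 0.712 for Mdm2 siRNA, 0.491 for EZH2 siRNA and 0.528 for their difference. HOX genes differed by 0.38, intestinal stem cell genes by 0.32, Wnt/beta-catenin targets by 0.47 and mesenchymal transition genes by 0.44, all higher after EZH2 siRNA. Cytosolic ribosomal protein genes differed by -0.20, and by 0.12 without EZH2 siRNA replicate 1.

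Ribosomal protein genes, which are among the brightest on the array, were lower after both knockdowns, at a median of -0.45 after EZH2 siRNA and -0.28 after Mdm2 siRNA, and a compressed signal range could lower all bright genes alike. For EZH2 siRNA replicate 1 the median of -0.68 lay at percentile 0 of 10000 lists of other genes of the same brightness (matched median -0.36). After quantile normalization it was -0.30 against 0.13. Matched genes do not move together as ribosomal protein genes do, so the matched range is too narrow for the percentile to decide. Compression thus stays open as the cause here. For replicate 2 compression stays open, since its median of -0.16 lay at percentile 29.03 of the matched lists (matched median -0.14), though at percentile 0.33 after quantile normalization. For Mdm2 siRNA it also stays open: the list lay at percentile 0.81, and at percentile 0.49 after quantile normalization (-0.04 against 0.03), but matched genes do not move together as ribosomal protein genes do (estimated correlation 0.656), and quantile normalization ended the call. A fall of ribosomal protein transcripts in EZH2 siRNA replicate 1 is thus a hypothesis from a single array.

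EZH2 siRNA replicate 1 lay farther from the controls than replicate 2, with 3391 against 2072 genes at least 2-fold from the control siRNA array, and the HOX and Wnt changes rested on it. A general difference between the slides is argued against, since the difference between slides in the EZH2 siRNA arrays correlated at 0.058 across genes with that in the Mdm2 siRNA arrays. Weaker signal on the array of replicate 2 stays open. The mean log2 signal of spike-in control probes was 11.514 on that array, against 12.228 for replicate 1. Among the brightest of 3 equal groups of genes, changes in replicate 2 spread 0.789 times as far as those of replicate 1. The bootstrap interval was 0.769 to 0.807. This cannot decide, since a weaker signal could narrow changes at every brightness. With a single array per replicate, the interval does not cover variation between arrays. Deeper loss of EZH2 in replicate 1 may contribute, as its EZH2 signal differed by -0.487 from that of replicate 2, but a single pair of arrays leaves this open. Different siRNA sequences also stay open and untested, because the labels mention EZH2 siRNAs from several sources without assigning them to arrays.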

How the results depend on the processing

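Normexp on median signals, the adjusted p of 0.1, and for the lists slide block, median centring and left-out arrays, were chosen after seeing the data. The 2 genes called for Mdm2 siRNA became 0 under normexp, quantile normalization, median centring, the authors' values, no filter, slide as a block, either control array alone, the mean of both control arrays in 4 groups, and the 4 arrays of 2 arms alone, and 1 with all 6 arrays above background or with an intensity trend and robust moderation. Leaving out arrays gave 0 to 0. The 0 genes of EZH2 siRNA (limma, 3551 at an unadjusted p under 0.05) became 4 with all 6 arrays above background, 3 with trend and robust moderation, 279 at an adjusted p of 0.1, and 0 to 758 when arrays were left out, the 758 without EZH2 siRNA replicate 2. EZH2 siRNA against Mdm2 siRNA (1805 at an unadjusted p under 0.05) and p53 siRNA against control siRNA (218) gave 0 under each alternative run. MDM2 changed by -0.496 by its weakest probe (adjusted p = 0.186 over the 3 targets). The correlation of the knockdowns was 0.442 and 0.421 with separate control arrays, which removes what a shared control adds, and 0.501 to 0.687 with arrays left out. Called lists numbered 5 for Mdm2 siRNA, 8 for EZH2 siRNA and 5 for their difference. They became 0, 0 and 0 with an estimated correlation, and 0, 0 and 0 with the directional test of fry, which tests each list alone. The mixed test of fry, added after seeing the data, which asks whether members change either way and not whether they change more than other genes, called 0, 10 and 5. Against the control siRNA array alone the numbers were 3 and 5 for the knockdowns, and quantile normalization gave 5 for EZH2 siRNA. With arrays left out the ranges were 3 to 6, 5 to 9 and 3 to 8. The interferon median for Mdm2 siRNA reversed to -0.12 without Mdm2 siRNA replicate 1 and was 0.887 without replicate 2, and the ribosomal difference between knockdowns reversed to 0.123 without EZH2 siRNA replicate 1 and was -0.471 without replicate 2. Of 172 genes by comparison taken by the naming rules, 169 kept their direction in every alternative run, and 3 did not. Many were chosen for both arrays lying beyond the other arm, so leaving out an array could not reverse them. The count is therefore no measure of stability. Where no cause is given, the cause was not tested. Signal limits the dim genes, since only 67.8% to 71.1% of spots per array were well above background.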

Other observations

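The test of separate control arrays was planned, while the other tests in this part, and the choice of genes, came after the results were seen. LIN28B and HMGA2, which are linked through let-7 microRNAs, were both higher after each knockdown. LIN28B stood at 2.88 after Mdm2 siRNA and 1.63 after EZH2 siRNA, at least 3.02-fold and 1.27-fold higher. HMGA2 stood at 1.75 and 3.06 by its brightest probe, but its other probes lay between -0.33 and -0.21 after Mdm2 siRNA and between -0.39 and 0.56 after EZH2 siRNA, so the change concerns the sequence of 1 probe. CDKN1A, the cell cycle inhibitor p21 and a target of p53, stood at 0.72 after Mdm2 siRNA and 1.04 after EZH2 siRNA in these cells without p53, and at 0.77 on the p53 siRNA array against the control siRNA array. CCNE2, a cyclin of S phase entry, stood at 1.63 and 1.56, yet at 0.28 and 0.56 on slide 1 and 2.98 and 2.57 on slide 2, with an SD of 1.24 between the 2 control-arm arrays.

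KRT20, a keratin of differentiated intestinal cells, was at -2.04 on the array of Mdm2 siRNA replicate 1, against -5.70 on the control siRNA array, and was not above background on the array of replicate 2. The interferon-stimulated genes were likewise higher on slide 1, which holds replicate 1, with a median of 0.60 against -0.02.

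Both knockdowns moved away from both controls in the same direction, by a covariance of 0.182 against 0.0843 simulated from shared control arrays alone. Noise of the shared control arrays is argued against as the whole cause, since r was still 0.302 in the lower of the array pairs with no common control array or slide. Compression of the signal range is argued against as well, since r was 0.41 in the lower of the control splits after quantile normalization. The position of an array on its slide cannot be told apart from its arm, because 0 arms had arrays at more than 1 position. A biological overlap, through PRC2 or as a general response to losing an essential regulator, may explain the rest and was not tested separately, since the only other active siRNA, against p53, has a target that makes no protein in these cells.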
